A study of Homo sapiens with 3 samples.

How the data were processed

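H460 cells and the derivatives mdR-H460 and ldR-H460 were each profiled as 1 library of single cells. Per the labels' protocols, cell suspensions were passed through a 30 µm strainer, loaded on a Chromium system with 5000 cells targeted, made into barcoded 3' libraries with chemistry version 2 and sequenced on a HiSeq 2500. Cell Ranger 3.0.2, Seurat 3.0 and the genome build GRCh38 are named in the submitters' processing notes, without the role of each, and the gene annotation release is not given in the sources used here. The labels name the derivatives mid-term and long-term, and what the codes in the sample descriptions stand for is not given in the sources used here, so no time was assigned.

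The deposited tables hold UMI counts per gene symbol and cell for cells that, per the series design text, the authors had kept after quality filtering. The values were whole numbers without normalization. Every cell had at least 201 detected genes and a mitochondrially encoded share under 10%. The most genes in a cell were 4987, 4993 and 3998 in H460, mdR-H460 and ldR-H460. Whether an upper limit on detected genes was set for each table is not given in the sources used here. The tables listed 17414, 17167 and 16837 symbols, 18692 in any and 15689 in all 3. Nearly all listed symbols (17329, 17053 and 16639) had UMIs in 3 or more cells, so a symbol that a table does not list may have had a few UMIs. Such a symbol was set to 0. Among listed symbols seen in 1 or 2 cells, 85 of 85, 113 of 114 and 195 of 195 had at most 3 UMIs, which is the floor used for bounds.

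UMIs were summed over all cells of a library and divided by the library total to give CPM. A floor of 3 UMIs per library stood for a count of 0, equal to 0.0453, 0.0450 and 0.0496 CPM in H460, mdR-H460 and ldR-H460, and folds against it are written as at least that size. No fold was given where both libraries were at or under the floor. Sums have exact Poisson intervals and ratios exact binomial-based intervals at 95%, all for counting error only. With 1 library per group no p-value or standard error was computed. Genes at 10 CPM or more in the higher library of a pair were counted as at least 2-fold higher or lower. Over the 3 libraries, genes at 10 CPM or more in at least 1 library were sorted into transient (at least 2-fold in mdR-H460 and within 1.5-fold in ldR-H460, both against H460), held (at least 2-fold in both, in the same direction), late (at least 2-fold in ldR-H460 and within 1.5-fold in mdR-H460) and opposite courses.

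Gene lists, 43 in number, were fixed together with the comparisons, the naming rule and the main alternatives before the data were examined. A member was measured at 1 CPM or more in at least 1 library. Each list has the median log2 CPM ratio of its measured members, the number of members at least 1.5-fold higher, lower or between, and the percentile of the median among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these libraries and is not a test. Intervals of medians come from 200 Poisson resamplings of the counts.

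The genes named are, for each pair, the 10 with the highest and the 10 with the lowest ratio at 10 CPM or more, leaving out mitochondrially encoded and ribosomal protein genes, sex-linked markers and numbered transcripts without a gene name. They are joined by up to 4 measured members of each list with the largest ratio in either direction, by all measured efflux, pluripotency and DNA methylation genes, by the 6 leading genes of each course in each direction, and by a fixed set of genes for the shares of cells. Some genes that the rule names are not reported here. Left out by the naming rule were 20, 35 and 21 genes at least 2-fold apart for mdR-H460 against H460, ldR-H460 against H460 and ldR-H460 against mdR-H460. Chromosome positions come from a match of symbols to GENCODE annotation on GRCh38, which may differ from the annotation the submitters used.

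For shares of cells and for phase calls each cell was thinned at random to 5000 UMIs, and 681, 1271 and 435 shallower cells of H460, mdR-H460 and ldR-H460 (15.0%, 24.7% and 8.78%) were left out. Shares have exact Clopper-Pearson 95% intervals. Phases were called with the S phase and G2/M lists in scanpy 1.11.5. For clusters, genes seen in 10 or more cells were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 were used without batch correction. Doublets were scored with a re-implementation of the Scrublet method (2 simulated doublets per cell, expected rate 5%). It marked 2, 6 and 4 cells (0.0441%, 0.116% and 0.0807%), which is too few for the caller to have worked, and all cells were kept. Cells with under 1000 UMIs (8.03%, 11.4% and 4.40%) were also kept.

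Alternatives covered edgeR TMM and DESeq2 scaling factors, totals without mitochondrially encoded and ribosomal protein UMIs, equal weight per cell, thinned cells, cells without the 5% with the most and the 5% with the fewest UMIs, without marked doublets, without cells carrying 3 fibroblast collagens, cells called G1 (no check of the S phase and G2/M lists, from which the call is made), expression floors of 1 CPM, 50 CPM and above 3 UMIs, list members at 10 CPM, other thinning depths, centred phase scores, and another cluster resolution. Chosen after the data had been seen were cells under 4000 detected genes, cells at 1000 UMIs or more, and all cells outside the H460 cluster led by S100A8 or outside the cluster led by HSPA6. The ratio, count and course steps were tested on simulated data for mdR-H460 against H460 with 6257 genes run. Of genes simulated 3-fold higher 50 of 50 were counted as at least 2-fold apart, and of those simulated 3-fold lower 49 of 49 run. Of those simulated 1.5-fold higher 0 of 50 were counted, of those simulated 1.5-fold lower 0 of 49 run, and of unchanged genes 0 of 6059. In each lower group 1 of the 50 genes drawn fell under 10 CPM and was not run. The simulated libraries held counting error alone, which is small at 10 CPM or more, so these results check the computation only. They do not cover differences between single cultures, and of the courses only the held ones were simulated.

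Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.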

Results

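To compare a lung carcinoma line with derivatives obtained through reprogramming, single-cell RNA sequencing was carried out on 3 cultures. H460 is an established human line from a large-cell lung carcinoma. The derivatives are called mid-term and long-term dR-H460 in the labels and are written here as mdR-H460 and ldR-H460. Each culture gave 1 library, so no test between groups was possible, no difference has a replicate check, and every ratio describes a pair of libraries. The H460, mdR-H460 and ldR-H460 libraries held 4531, 5151 and 4956 cells, and their sum of 14638 equals the number of cells in the series design text. They held 66192074, 66624830 and 60468481 UMIs in the same order. The median cell had 14685, 11736 and 12342.5 UMIs and 3083, 2503 and 2673 detected genes. Mitochondrially encoded transcripts took 4.80%, 5.21% and 6.80% of all UMIs. Levels are given as CPM, the UMIs of a gene scaled to the total of its library, and the range after a fold is its 95% counting interval, which covers counting error only. Gene positions refer to GRCh38.

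To find out how mdR-H460 differed from the parental line, CPM ratios were compared over 6402 genes at 10 CPM or more in the higher library. The highest ratio belonged to PKIB, an inhibitor of protein kinase A (chromosome 6, 122471917 to 122726373), with 28.7 CPM in mdR-H460 against 0.151 in H460, 190.0-fold (103 to 397) higher. DSP, which encodes the desmosomal plaque protein desmoplakin (chromosome 6, 7541575 to 7586717), was 61.4-fold (36.4 to 113) higher. The fibrinogen chain genes were also higher, FGA (chromosome 4, 154583126 to 154590766) by 46.0-fold (36.9 to 58.0) at 56.3 CPM and FGG (chromosome 4, 154604134 to 154612967) by 7.95-fold (7.59 to 8.34) at 233 CPM. An H460 cluster of 247 cells (5.45%), led by S100A8, was left out in an alternative chosen only after the values were seen. It held 77.8% of the FGA and 61.9% of the FGG UMIs of H460. Without it FGA was 194-fold (122 to 327) higher, with 18 UMIs left in H460, and FGG 19.5-fold (18.2 to 21.1) higher. These larger folds follow from leaving out the H460 cells that held most UMIs of both genes. All mdR-H460 cells were kept in that comparison, among them a cluster of 866 cells that was also led by S100A8. HPD, an enzyme of tyrosine breakdown, was 35.6-fold (25.1 to 52.4) higher, and the cytokine gene IL11 reached 20.1 CPM from 0.680, 29.6-fold (22.02 to 40.8) higher. FAM162B, IFITM1, FAM83A, SAMD11 and ECEL1 completed the upper 10, between 15.6-fold and 62.1-fold higher. At the other end stood CDH11, a cadherin of mesenchymal cells (chromosome 16, 64943753 to 65126112), with 167 CPM in H460 and 8 UMIs in mdR-H460, 1387-fold (704 to 3213) lower. MMP1, the interstitial collagenase (chromosome 11, 102789920 to 102798160), had 16.6 CPM in H460, was not listed for mdR-H460, and was at least 369-fold lower. FGF13, LSAMP and RTN1, known from neurons, were 322-fold (184 to 624), 172-fold (93.2 to 359) and 74.1-fold (48.8 to 119) lower. PAEP, which encodes the secreted lipocalin glycodelin (chromosome 9, 135561756 to 135566955), was 93.3-fold (75.0 to 118) lower, and the class II antigen gene HLA-DRB1 was 113-fold (65.6 to 212) lower, a count that is uncertain because near-identical copies exist. PRKCDBP, TSTD1 and SLC38A5 were 208-fold, 114-fold and 82.7-fold lower.

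Over all measured genes, 117 were at least 2-fold higher and 451 at least 2-fold lower in mdR-H460 than in H460, so 79.4% of these genes were lower, while 5007 genes (78.2%) lay within 1.5-fold. At least 4-fold differences were found for 38 genes higher and 110 lower. The median log2 ratio of all genes was -0.10. TMM and DESeq2 factors added 0.19 and 0.18 to every log2 ratio of this pair, and the lower share was then 64.5% and 65.1%. With cells called G1 alone it was 68.9%.

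Several gene groups fixed beforehand had low medians in mdR-H460. Members were counted as higher or lower at 1.5-fold. The range after a list's median spans its values under the alternatives of processing, leaving out G1 cells for the S phase and G2/M lists from which they were called, and the percentile places a list's median among 10000 random lists of matched size and expression. Among cancer stem cell surface and self-renewal markers, 7 of 11 measured members were at least 1.5-fold lower and 0 higher (median log2 ratio -1.44, range -1.58 to -1.26, percentile 0.00). Of these, CD24 was 13.9-fold (12.8 to 15.1) lower, LGR5, a WNT receptor component of stem cells, 12.4-fold (5.75 to 31.7) lower and the laminin receptor subunit ITGA6 4.25-fold (3.84 to 4.71) lower. MHC class I presentation genes were lower in 8 of 14 and higher in 0 (median log2 ratio -0.80, range -0.83 to -0.46, percentile 0.00, -0.46 with G1 cells), with HLA-B 4.09-fold (3.87 to 4.32), HLA-C 2.16-fold (2.08 to 2.24) and the immunoproteasome subunit gene PSMB9 3.04-fold (2.83 to 3.27) lower. The class I heavy chain genes are highly similar to one another, so their separate counts are uncertain. Growth factor receptors and ligands were lower in 9 of 15 and higher in 0 (median log2 ratio -0.84, range -0.90 to -0.21, percentile 0.01), with the median nearest to no difference among cells called G1, led by PDGFA at 4.25-fold, IGFBP3 at 4.05-fold and ERBB2 at 3.15-fold lower. Cell adhesion and extracellular matrix genes were lower in 13 of 20 and higher in 2 (median log2 ratio -0.72, range -0.73 to -0.54, percentile 0.02), including the collagen VI chain gene COL6A1, 8.13-fold (6.52 to 10.2) lower, and L1CAM, 5.59-fold (4.17 to 7.62) lower. ERK pathway output genes were lower in 9 of 18 and higher in 1 (median log2 ratio -0.54, range -0.60 to -0.23, percentile 0.38), with the feedback regulator SPRY2 3.37-fold (3.01 to 3.77) lower. Chromatin remodelling genes were lower in 8 of 21, none higher at 1.5-fold (median log2 ratio -0.47, range -0.58 to -0.28, percentile 0.14), led by the helicase gene CHD1 at 2.71-fold (2.56 to 2.86) lower. Mesenchymal and EMT genes went both ways, 7 lower and 1 higher of 18 (median log2 ratio -0.30, range -0.47 to -0.03, percentile 2.89), with the repressor ZEB2 24.4-fold (18.6 to 32.7) lower and the tropomyosin gene TPM2 6.49-fold (6.19 to 6.80) higher.

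Other groups were higher in mdR-H460 or split. Unfolded protein and amino acid stress genes were higher in 9 of 22 and lower in 2 (median log2 ratio 0.42, range 0.34 to 0.62, percentile 100.00), with asparagine synthetase ASNS 2.47-fold (2.28 to 2.67), the stress factor DDIT3 1.84-fold (1.76 to 1.93) and the serine pathway enzyme SHMT2 1.77-fold (1.70 to 1.85) higher. A small cluster led by HSPA6 held 70.3% of the DDIT3 UMIs of H460 and 75.7% of those of mdR-H460. Without it, a choice made after the values were seen, DDIT3 was 1.51-fold (1.38 to 1.66) higher. NRF2 targets were higher in 3 of 23 and lower in 0 (median log2 ratio 0.27, range 0.15 to 0.46, percentile 99.8), among them haem oxygenase HMOX1 at 2.43-fold (2.28 to 2.59) higher. G2/M genes were higher in 10 of 52 and lower in 2 (median log2 ratio 0.22, range 0.09 to 0.41, percentile 100.00), with the cyclin gene CCNB2 2.57-fold (2.43 to 2.73) and the kinetochore histone gene CENPA 2.11-fold (1.97 to 2.26) higher, whereas S phase genes were lower in 13 of 43 and higher in 0 (median log2 ratio -0.31, range -0.44 to -0.12, percentile 0.95), led by CCNE2 at 2.81-fold (2.40 to 3.30) lower. Of 8 measured keratin and squamous genes, 4 were higher and 1 lower (median log2 ratio 0.69, range 0.31 to 1.26, percentile 99.99, 0.31 with cells weighted equally and 1.26 without the H460 cluster led by S100A8), with S100A2 2.72-fold (2.61 to 2.83) higher and KRT81, whose reads may be shared with KRT86, 3.94-fold (3.58 to 4.34) higher, or 7.22-fold higher without the H460 cluster led by S100A8. KRT81, S100A8 and S100A9 of this list were among the leading genes of that cluster, which was left out of H460 alone. The larger fold of KRT81 without it therefore follows from the choice. Inflammatory and NF-kB genes were higher in 9 of 21 and lower in 5 (median log2 ratio 0.20, range -0.09 to 0.39, percentile 99.6), and the median took the other sign with cells weighted equally, with thinned cells and with members at 10 CPM. Within this group the adhesion receptor ICAM1 was 6.78-fold (5.18 to 8.998) higher and the cytokine IL6 3.10-fold (2.98 to 3.22) lower. Epithelial genes were split, 5 higher and 4 lower of 13 (median log2 ratio -0.21, range -0.22 to 0.57, percentile 24.9), and their median turned positive with thinned cells, trimmed cells, G1 cells, cells under 4000 genes or members at 10 CPM. KRT19, an abundant keratin (chromosome 17, 41523617 to 41528308), had 1696 CPM in H460 and 194 in mdR-H460, 8.74-fold (8.58 to 8.90) lower.

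To find out how the long-term derivative differed from the parental line, ldR-H460 was compared with H460 over 6556 genes. OLFML3, a secreted olfactomedin-domain protein gene (chromosome 1, 113979391 to 114035572), had 18.9 CPM in ldR-H460, was not listed for H460, and was at least 418-fold higher. PKIB was 151-fold (82.1 to 316) higher and HPD (chromosome 12, 121839527 to 121863596) 55.7-fold (39.3 to 81.7) higher, both also among the 10 highest ratios of mdR-H460. ANKRD1, a target of YAP signalling, reached 97.3 CPM from 2.37, 41.0-fold (35.0 to 48.4) higher. The inhibitor of differentiation gene ID4 was 34.3-fold (25.7 to 46.7) higher, the cytokine gene IL18 13.9-fold (11.8 to 16.6) higher, and FAM181B 106-fold (53.7 to 247) higher. GPR141, ATOH8 and ANKRD2 were between 13.8-fold and 16.1-fold higher. The lower end held PAEP, which had 113 CPM in H460, was not listed for ldR-H460 and was at least 2287-fold lower. S100A8 and S100A9, which encode the subunits of calprotectin (chromosome 1, 153390032 to 153391188 and chromosome 1, 153357854 to 153361027), were 469-fold (289 to 822) and 170.2-fold (143 to 204) lower, S100A9 at 363 CPM in H460 and 2.13 in ldR-H460. The H460 cluster led by S100A8 held 96.0% of the S100A8 and 82.9% of the S100A9 UMIs of H460, and without it these genes were 20.1-fold and 31.2-fold lower in ldR-H460. The lipocalin gene LCN1 was 387-fold (283 to 544) lower, the endothelial and tumour proteoglycan gene ESM1 223-fold (117 to 489) lower, the inducible heat shock gene HSPA6 166-fold (84.3 to 386) lower and the neural adhesion gene NCAM1 132-fold (63.6 to 328) lower. A cluster of 222 cells led by HSPA6 and DDIT3, left out only after the values were seen, took in 1.54% of H460, 2.95% of mdR-H460 and 0% of ldR-H460 cells and held 95.1% of the HSPA6 UMIs of H460, and without it HSPA6 was 8.31-fold lower in ldR-H460. MMP1, HLA-DRB1 and the ammonium transporter gene RHCG were not listed for ldR-H460 and were at least 335-fold lower, at least 443-fold lower and at least 249-fold lower.

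In this pair 218 genes were at least 2-fold higher and 523 at least 2-fold lower in ldR-H460, a lower share of 70.6%, and 4752 genes (72.5%) lay within 1.5-fold. The median log2 ratio of all genes was -0.12. TMM and DESeq2 factors added 0.12 and 0.10 to every log2 ratio, with lower shares of 59.2% and 61.1%. The cells of ldR-H460 all had fewer than 4000 detected genes, whereas 681 cells of H460 and 504 of mdR-H460 had 4000 or more, and 718 of the 741 genes were called in the same direction when such cells were left out everywhere.

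Gene groups with low medians in ldR-H460 were led by keratins and squamous genes, with 5 of 8 lower and 2 higher (median log2 ratio -1.91, range -1.92 to -1.65, percentile 0.00). Epithelial genes were lower in 9 of 13 and higher in 2 (median log2 ratio -0.94, range -1.02 to -0.42, percentile 0.03, -0.42 with members at 10 CPM), with KRT19 42.1-fold (40.4 to 43.8) lower and the laminin chain gene LAMB3 55.4-fold (23.5 to 172) lower, against DSP at 34.1-fold (20.1 to 62.9) higher. Inflammatory and NF-kB genes were lower in 11 of 21 and higher in 5 (median log2 ratio -0.90, range -1.17 to -0.53, percentile 0.00), with a median of -0.54 without the cluster led by HSPA6 and -0.53 without the H460 cluster led by S100A8. The neutrophil chemokine CXCL1 (chromosome 4, 73869393 to 73871242) had 3410.4 CPM in H460 and 461 in ldR-H460, 7.40-fold (7.31 to 7.497) lower, IL6 was 18.4-fold (16.9 to 20.1) lower and IL1B 17.2-fold (13.6 to 22.3) lower, while CCL2 was 10.4-fold (6.20 to 18.7) higher. Immediate early genes were lower in 10 of 17 and higher in 2 (median log2 ratio -0.96, range -0.99 to -0.28, percentile 0.00), among them KLF2 at 5.29-fold (4.88 to 5.74) and IER3 at 2.77-fold (2.69 to 2.85) lower, and their median was -0.28 without the cluster led by HSPA6. MHC class I presentation genes were lower in 10 of 14 and higher in 0 (median log2 ratio -0.81, range -0.89 to -0.69, percentile 0.02), with HLA-B 7.71-fold (7.16 to 8.32) lower. Stem cell surface and self-renewal markers were lower in 6 of 11 (median log2 ratio -1.09, range -1.21 to -0.66, percentile 0.00), growth factor receptors and ligands in 7 of 15 (median log2 ratio -0.56, range -0.70 to -0.22, percentile 0.86) and adhesion and matrix genes in 9 of 20 (median log2 ratio -0.51, range -0.52 to -0.28, percentile 0.78). The EGFR ligand genes AREG and EREG were 12.6-fold (11.1 to 14.5) and 13.7-fold (8.23 to 24.3) lower, and the matrix gene COL12A1 was 22.3-fold (14.4 to 36.4) higher. Proteasome subunit genes were lower in 11 of 37 and higher in 0 (median log2 ratio -0.38, range -0.52 to -0.26, percentile 0.07), with PSMD12 2.02-fold (1.94 to 2.11) lower. Targets of p53 were lower in 9 of 20 and higher in 1 (median log2 ratio -0.33, range -0.52 to -0.09, percentile 6.90, -0.09 with G1 cells), although CCNG1 was 3.10-fold (2.97 to 3.23) higher. S phase genes were lower in 11 of 43 (median log2 ratio -0.36, range -0.38 to -0.24, percentile 0.66).

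Higher medians in ldR-H460 belonged to mitochondrially encoded genes, 3 higher and 0 lower of 13 (median log2 ratio 0.47, range 0.46 to 0.59, percentile 99.9), with MT-ATP6 1.80-fold (1.79 to 1.80) higher. NRF2 targets were higher in 6 of 23 and lower in 2 (median log2 ratio 0.36, range 0.33 to 0.48, percentile 99.9), with the ferritin light chain gene FTL, which has many pseudogenes, 2.38-fold (2.38 to 2.39) higher, AKR1C2, a near-identical copy of AKR1C1, 2.25-fold (2.18 to 2.31) higher and AKR1B10 2.43-fold (2.39 to 2.47) lower. G2/M genes were higher in 10 of 52 and lower in 3 (median log2 ratio 0.23, range 0.21 to 0.43, percentile 100.00). Notch pathway genes were higher in 5 of 11 and lower in 2 (median log2 ratio 0.32, range -0.44 to 0.63, percentile 99.2), led by HEY1 at 7.08-fold (5.38 to 9.45) and the ligand gene JAG1 at 4.05-fold (3.17 to 5.22) higher, and the median was negative among members at 10 CPM. YAP and TGF-beta target genes were higher in 5 and lower in 3 of 16 (median log2 ratio 0.17, range 0.12 to 0.30, percentile 96.7), with THBS1 4.58-fold (3.38 to 6.31) higher and PMEPA1 10.5-fold (8.47 to 13.1) lower. Unfolded protein and amino acid stress genes were split, 8 higher and 5 lower of 22 (median log2 ratio -0.14, range -0.21 to 0.23, percentile 39.1, positive with members at 10 CPM and without the cluster led by HSPA6), with ASNS 2.50-fold (2.31 to 2.70) higher and DDIT3 4.05-fold (3.71 to 4.43) lower. That cluster held 70.3% of the DDIT3 UMIs of H460 and 75.7% of those of mdR-H460, and without it DDIT3 was 1.22-fold lower in ldR-H460.

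**Figure D1:**
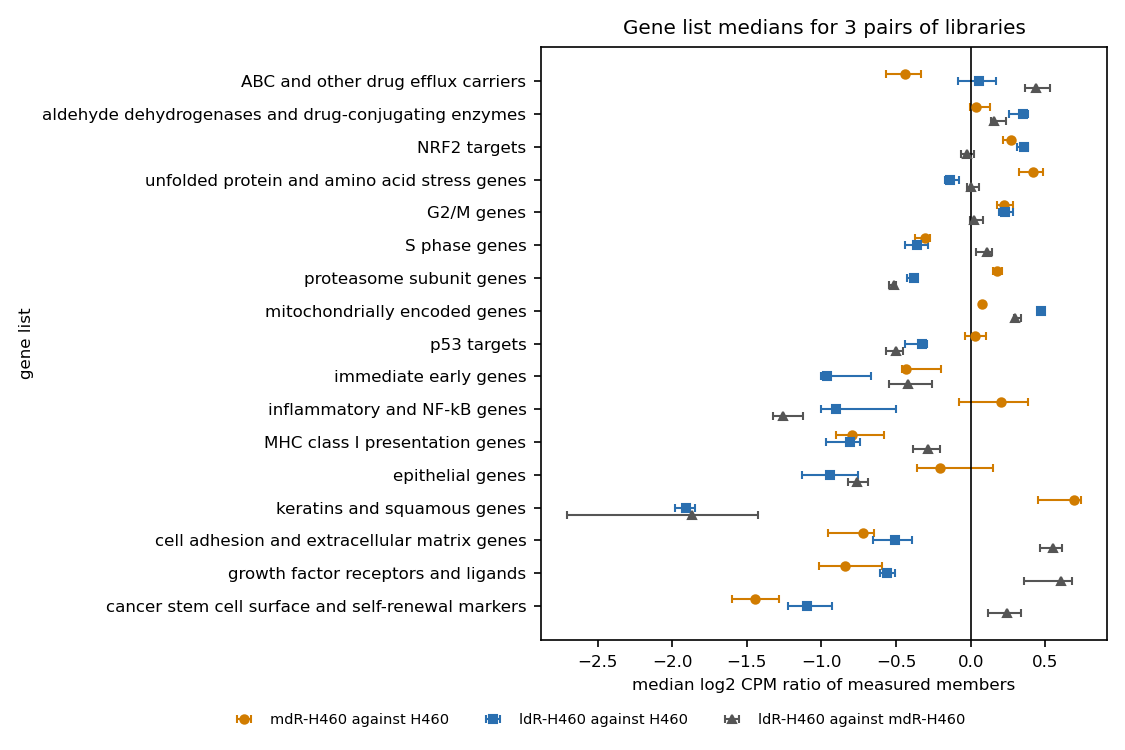
Median log2 CPM ratio of the measured members of 17 gene lists for each pair of libraries, with bars spanning 95% of 200 resamplings of the counts. The keratin and squamous list stands at 0.69 in mdR-H460 and -1.91 in ldR-H460 against H460, and stem markers at -1.44 and -1.09. Several medians drawn change sign under an alternative. For ldR-H460 against mdR-H460 these include G2/M and unfolded protein genes with TMM and DESeq2 factors. In that pair they also include NRF2 targets without mitochondrially encoded and ribosomal protein UMIs and with G1 cells, and immediate early genes without the cluster led by HSPA6. For mdR-H460 against H460 they include the efflux, drug-conjugating, inflammatory, epithelial and immediate early lists.

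To set the derivatives against each other, ldR-H460 was compared with mdR-H460 over 6189 genes. CDH11 was 100.1-fold (50.5 to 233) higher in ldR-H460, where it reached 12.02 CPM, and OLFML3 was 66.4-fold (42.3 to 111) higher. RTN1, SCN9A and IGFBP7 were 63.9-fold (42.0 to 102), 14.5-fold (11.3 to 18.97) and 10.1-fold (7.92 to 12.9) higher, and their levels in ldR-H460 of 21.1, 14.2 and 11.3 CPM compare with 24.5, 8.82 and 18.9 CPM in H460. The transcription factor gene TOX2 and the peptide ligand gene APLN were 6.30-fold (5.26 to 7.60) and 8.28-fold (6.65 to 10.4) higher. S100A8 was 320.3-fold (197 to 561) lower and S100A9 238-fold (201 to 286) lower in ldR-H460. ECEL1, an endopeptidase-like gene, was 108-fold (60.0 to 216) lower, IL11 (chromosome 19, 55364389 to 55370463) 55.4-fold (36.4 to 88.6) lower and FGG 19.2-fold (17.8 to 20.7) lower. ESM1, LCN1, IGFN1 and CDCP1 were between 15.6-fold and 82.3-fold lower.

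Between the derivatives 159 genes were at least 2-fold higher and 191 at least 2-fold lower in ldR-H460, a lower share of 54.6%, and 5013 genes (81.0%) lay within 1.5-fold. The median log2 ratio was 0.00. TMM and DESeq2 factors lowered every log2 ratio of this pair by the same shift, -0.07, and the lower share was 61.0% and 61.8%, whereas it was 43.9% when mitochondrially encoded and ribosomal protein UMIs were left out of the totals.

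Keratins and squamous genes were lower in 6 of 8 with 0 higher (median log2 ratio -1.87, range -2.70 to -1.64, percentile 0.00), inflammatory and NF-kB genes lower in 14 of 21 (median log2 ratio -1.26, range -1.40 to -1.13, percentile 0.00), and epithelial genes lower in 8 of 13 (median log2 ratio -0.76, range -1.07 to -0.67, percentile 0.00). Proteasome subunit genes were lower in 16 of 37 and higher in 0 (median log2 ratio -0.52, range -0.59 to -0.47, percentile 0.00), with the ATPase subunit gene PSMC4 1.99-fold (1.92 to 2.06) lower. Targets of p53 were lower in 8 of 20 and higher in 1 (median log2 ratio -0.50, range -0.62 to -0.36, percentile 0.00), led by the stress cytokine GDF15 at 3.97-fold (3.80 to 4.14) lower. Hypoxia and glycolysis genes were lower in 8 of 25 and higher in 2 (median log2 ratio -0.40, range -0.52 to -0.34, percentile 0.00), with the carbonic anhydrase gene CA9 12.2-fold (6.92 to 23.3) lower and the glucose transporter gene SLC2A3 2.90-fold (2.51 to 3.37) higher. Heat shock genes were lower in 3 of 14 and higher in 0 (median log2 ratio -0.35, range -0.71 to -0.18, percentile 0.72, -0.71 with G1 cells and -0.18 without the cluster led by HSPA6). Higher in ldR-H460 were growth factor receptors and ligands, 8 higher and 3 lower of 15 (median log2 ratio 0.61, range 0.29 to 0.65, percentile 99.98, 0.29 with G1 cells), with NRG1 3.61-fold (3.31 to 3.95) and IGFBP3 2.75-fold (2.62 to 2.90) higher. Adhesion and matrix genes were higher in 9 and lower in 3 of 20 (median log2 ratio 0.55, range 0.39 to 0.57, percentile 99.99), with COL12A1 13.5-fold (9.54 to 19.6) and L1CAM 3.96-fold (2.91 to 5.46) higher and the anchoring fibril gene COL7A1 13.4-fold (10.2 to 17.9) lower. The median of unfolded protein and amino acid stress genes was 0.00 and turned negative with TMM and DESeq2 factors, cells weighted equally, thinned cells, trimmed cells, G1 cells or cells under 4000 genes, with 2 higher and 6 lower of 22, and DDIT3 was 7.46-fold (6.86 to 8.12) lower, or 1.85-fold lower without the cluster led by HSPA6.

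To ask which differences of mdR-H460 were also present in ldR-H460, 6641 genes at 10 CPM or more in at least 1 library were sorted by course. The course names stand for levels in 3 libraries by a size rule, and no time was assigned to the libraries. Of 130 genes at least 2-fold higher in mdR-H460 than in H460, 80 (61.5%) were also at least 2-fold higher in ldR-H460, 22 (16.9%) were within 1.5-fold of H460 there and 28 lay between or on the other side. Of 457 genes at least 2-fold lower, 299 (65.4%) were also at least 2-fold lower in ldR-H460, 64 (14.0%) were within 1.5-fold of H460 there and 94 were neither. Independent lists of these sizes would share 4.48 higher and 36.8 lower genes, and simulated unchanged libraries set against 1 shared parental library gave 0 in both directions. These libraries differed by counting error alone, so this 0 does not cover differences between single cultures. Part of the excess may come from the shared H460 library, which cannot be split. PKIB, FAM162B, DSP, FGA, HPD and IFITM1 led the genes higher in both derivatives, and CDH11, MMP1, FGF13, PRKCDBP, LSAMP and TSTD1 those lower in both.

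Transiently higher genes, within 1.5-fold of H460 in ldR-H460, included ADGRG3, an adhesion receptor gene, with 2.39, 25.7 and 2.22 CPM in H460, mdR-H460 and ldR-H460. The fibrinogen gene FGB followed the same order with 5.98, 32.9 and 6.53 CPM, a course that ended without the H460 cluster led by S100A8, where H460 had 3.55 CPM. The retinoid enzyme gene DHRS3 had 8.69, 35.6 and 12.8 CPM and the lysosomal ceramidase gene ASAH1 65.0, 200.05 and 45.6 CPM. UNC5D and SPINK13 were 5.17-fold and 3.51-fold higher in mdR-H460. Among transiently lower genes, RTN1 had 24.5, 0.330 and 21.1 CPM, ADGRG6 16.4, 2.16 and 11.3 CPM, the neuronal tubulin gene TUBB2B 10.4, 1.86 and 10.1 CPM, and IGFBP3 130.4, 32.2 and 88.6 CPM. P3H3 and STXBP6 were 4.31-fold and 4.25-fold lower in mdR-H460. Another 90 genes were higher and 111 lower in ldR-H460 alone, that is, within 1.5-fold in mdR-H460. These late genes included PDK4, a pyruvate dehydrogenase kinase gene, 6.76-fold (5.49 to 8.38) higher, the tau gene MAPT 4.76-fold (4.18 to 5.43) higher, and the protease inhibitor genes PI3 and SLPI, 15.1-fold (13.7 to 16.7) and 7.69-fold (7.30 to 8.11) lower. SERTAD4-AS1, STK32C, OGFRL1 and IFITM2 were between 3.47-fold and 5.87-fold higher late, and SDC2 and RHOH 6.96-fold and 6.64-fold lower. In 11 genes the derivatives went in opposite directions, among them ECEL1, 15.6-fold higher in mdR-H460 and 6.89-fold lower in ldR-H460, and FGG, 7.95-fold higher and 2.41-fold lower. For FGG this held only with the H460 cluster led by S100A8, without which it was 1.02-fold higher in ldR-H460. Both calprotectin subunit genes were late, S100A8 with 124, 84.7 and 0.265 CPM and S100A9 with 363, 509 and 2.13 CPM. Without the same H460 cluster, neither these genes nor PI3 and SLPI met the rule for a late course. Without it S100A8, S100A9, PI3 and SLPI were 15.9-fold, 7.65-fold, 1.63-fold and 2.21-fold higher in mdR-H460 than in H460, and PI3 and SLPI were 8.28-fold and 4.71-fold lower in ldR-H460. FGG, FGB and these 4 genes led that cluster, so their lower H460 levels without it follow from the choice. All mdR-H460 cells were kept, among them the cluster of 866 cells also led by S100A8, so no difference between the cultures is read from these folds. By group, 5 of 8 stem cell markers at 10 CPM or more were lower in both derivatives and 1 was transiently lower. Of 11 interferon-stimulated genes 4 were lower and 2 higher in both, and 2 were higher late. Of 11 MHC class I genes 3 were lower in both and 1 lower late. Of 16 inflammatory genes 3 were lower and 1 higher in both, 3 were lower late and 1 was transiently higher. The remaining 5964 genes had no such course, and the number of transiently higher genes was 38 with TMM and 37 with DESeq2 factors.

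**Figure D2:**
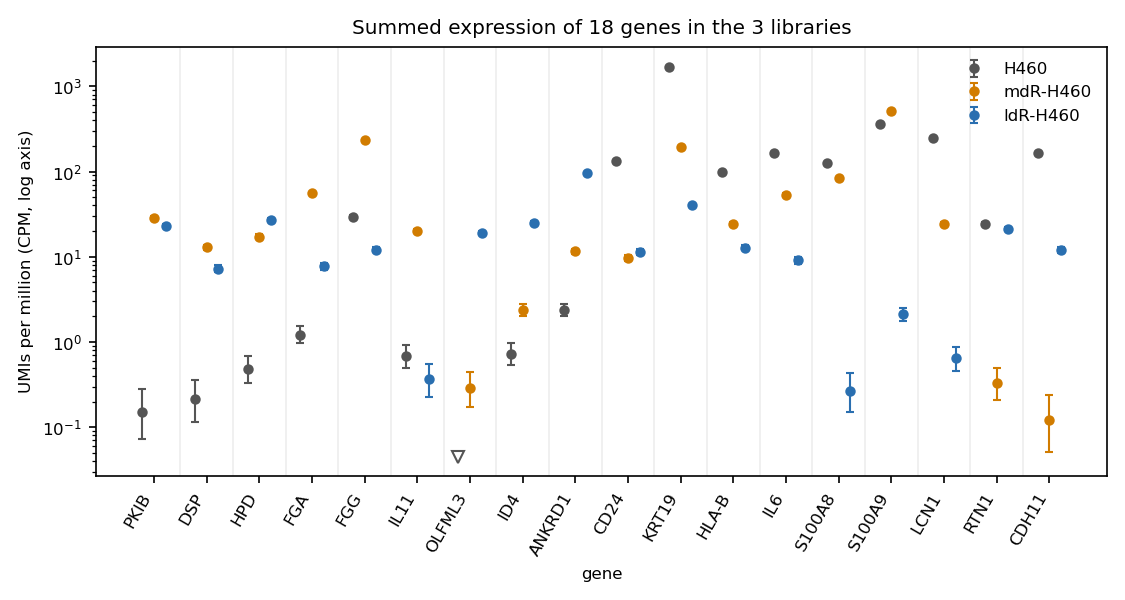
Level of 18 named genes in H460, mdR-H460 and ldR-H460 in CPM on a log axis, with 95% Poisson intervals as bars and an open triangle at 3 UMIs for a gene not listed for a library. CDH11 lies at 167, 0.120 and 12.02 CPM and S100A9 at 363, 509 and 2.13 CPM in that order.

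Since the series title names multi-drug resistance, drug efflux carriers and detoxifying enzymes were compared over the 3 libraries. Of 13 measured efflux carriers, 5 were at least 1.5-fold lower and 0 higher in mdR-H460 than in H460 (median log2 ratio -0.44, range -0.60 to 0.05, percentile 8.72), a median that was positive among members at 10 CPM. In ldR-H460 1 was higher and 2 lower (median log2 ratio 0.05, range 0.04 to 0.20, percentile 83.8), and against mdR-H460 4 were higher and 2 lower (median log2 ratio 0.44, range 0.36 to 0.48, percentile 97.5). ABCC3, an organic anion exporter, had 26.2, 35.6 and 50.7 CPM, 1.36-fold (1.28 to 1.45) and 1.94-fold (1.83 to 2.06) higher than in H460. ABCC2 was 1.10-fold (1.03 to 1.16) and 1.15-fold (1.08 to 1.22) higher, and ABCC5 1.23-fold (1.03 to 1.45) and 1.44-fold (1.22 to 1.70) higher. ABCC1 had 6.36, 4.88 and 6.60 CPM, ABCC4 3.70, 2.58 and 4.27, ABCC10 1.22, 1.28 and 1.42 and ABCB10 12.8, 9.44 and 13.2. ABCG2, the breast cancer resistance protein gene, was 2.21-fold (1.93 to 2.53) lower in mdR-H460 and 1.29-fold (1.15 to 1.45) lower in ldR-H460. ABCB1, which encodes P-glycoprotein, had 28, 19 and 2 UMIs in H460, mdR-H460 and ldR-H460, 12.8-fold (3.23 to 111) lower in ldR-H460 than in H460, and the interval of its ratio in mdR-H460, 0.356 to 1.25, includes 1. Without the cluster led by HSPA6 that interval was 0.195 to 0.926 and lay under 1, with 11 UMIs left in mdR-H460 and 25 in H460. The cluster held 42.1% of the ABCB1 UMIs of mdR-H460 and 10.7% of those of H460. The lower ratio without it therefore follows from the choice, and no difference is read from it. The lipid carrier genes ABCA2 and ABCA3 were 2.17-fold (1.74 to 2.73) and 2.83-fold (2.23 to 3.63) lower in mdR-H460, the copper carrier gene ATP7A 2.19-fold (1.69 to 2.86) lower and the vault protein gene MVP 2.94-fold (2.52 to 3.44) lower. MVP and ABCA3 were also lower in ldR-H460, by 5.06-fold (4.16 to 6.21) and 4.73-fold (3.48 to 6.54). Aldehyde dehydrogenases and drug-conjugating enzymes were higher in 4 and lower in 2 of 22 in mdR-H460 (median log2 ratio 0.04, range -0.05 to 0.22, percentile 79.5), a median with the other sign with cells weighted equally, with thinned cells and with members at 10 CPM, and higher in 7 and lower in 3 in ldR-H460 (median log2 ratio 0.35, range 0.12 to 0.47, percentile 99.9). ALDH1A1 was 1.93-fold (1.85 to 2.01) higher in mdR-H460 and 1.84-fold (1.73 to 1.95) lower in ldR-H460, and ALDH3A1 1.14-fold (1.10 to 1.16) and 2.14-fold (2.09 to 2.19) higher. The vitamin D hydroxylase gene CYP24A1 was 26.4-fold (16.7 to 44.1) and 13.9-fold (8.74 to 23.6) higher, and CYP1B1, a xenobiotic monooxygenase gene, 5.14-fold (5.01 to 5.28) and 4.58-fold (4.46 to 4.70) lower.

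To describe these levels per cell, each cell was thinned to 5000 UMIs, which left 3850, 3880 and 4521 cells of H460, mdR-H460 and ldR-H460. A UMI of ALDH1A1 was found in 20.3%, 32.3% and 10.99% of these cells, against 39.9%, 48.8% and 19.9% without thinning. For ALDH3A1 the shares were 38.9%, 47.2% and 66.3%, and 58.0%, 61.9% and 84.0% without thinning. ABCC3 was found in 13.2%, 19.02% and 22.7% of thinned cells and 29.1%, 32.8% and 43.3% of unthinned cells, and ABCG2 in 4.99%, 2.16% and 3.96%, and 13.2%, 5.67% and 8.84%. ABCB1 was found in 0.260% and 0.180% of thinned H460 and mdR-H460 cells and in 0 of 4521 ldR-H460 cells. The exact interval of this 0 allows a share of cells with a UMI of up to 0.0816%, and 3 counts of the total a share of up to 0.0664%. Without thinning the ABCB1 shares were 0.618%, 0.349% and 0.0404%. CD24 was found in 35.5%, 3.32% and 5.13%, and 48.7%, 5.59% and 8.82% without thinning. The libraries held no other cell type from which the share given by free RNA could be read.

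As the title also names an epigenetic mechanism and reprogramming, pluripotency genes and chromatin enzymes were examined next. Of 20 pluripotency genes 3 were measured. SOX2 had 0.680, 3.06 and 5.72 CPM, 4.50-fold (3.25 to 6.37) and 8.42-fold (6.16 to 11.8) higher than in H460, and was found in 0.571%, 1.21% and 2.81% of thinned cells and 0.927%, 3.51% and 5.95% of unthinned cells. MYC was 1.32-fold (1.26 to 1.38) and 1.69-fold (1.62 to 1.76) higher, and KLF4 3.05-fold (2.89 to 3.21) and 4.52-fold (4.24 to 4.82) lower. POU5F1 had 3 UMIs in mdR-H460 and was not listed for H460 or ldR-H460. The median log2 ratio of the 3 genes was 0.40 in mdR-H460 and 0.76 in ldR-H460 (percentiles 95.8 and 98.6). In both it was the ratio of MYC, which lay between SOX2 and KLF4, so the percentiles say little on the list as a group. The median of the 3 genes changed sign in mdR-H460 with cells weighted equally. Over the alternatives it ranged from -0.33 to 0.66 in mdR-H460 and from 0.22 to 1.41 in ldR-H460, where 0.22 was found with G1 cells. In the DNA methylation machinery 1 of 16 genes was higher and 3 lower in mdR-H460 (median log2 ratio -0.09, range -0.28 to 0.10, percentile 66.5), a median that was positive with TMM and DESeq2 factors, and 1 was higher and 1 lower in ldR-H460 (median log2 ratio -0.24, range -0.30 to -0.11, percentile 23.2). The maintenance methyltransferase gene DNMT1 had 100.2, 109 and 131 CPM and the de novo enzyme gene DNMT3A 2.27, 2.70 and 3.67. UHRF1, which recruits DNMT1, had 13.5, 12.98 and 12.8 CPM, and UHRF2 5.64, 4.50 and 4.99. The methyl-CpG binding domain family genes MBD1, MBD3 and MBD4 had 11.6, 20.2 and 26.7 CPM in H460 and lay within 1.5-fold of these levels in both derivatives, as did the helicase gene HELLS at 64.6 CPM and the glycosylase gene TDG at 79.8 CPM. MBD2 had 24.2, 16.9 and 28.1 CPM. The demethylation genes TET1, TET2 and TET3 had 6.62, 2.42 and 1.68 CPM in H460, 6.39, 1.40 and 0.931 in mdR-H460 and 4.91, 1.65 and 1.31 in ldR-H460. GADD45A was 1.52-fold (1.47 to 1.58) higher in mdR-H460 and 1.40-fold (1.34 to 1.47) lower in ldR-H460, and the methyl-CpG reader gene ZBTB38 1.54-fold (1.48 to 1.60) and 2.25-fold (2.14 to 2.36) lower. Histone methylation enzymes were higher in 1 and lower in 5 of 34 in mdR-H460 (median log2 ratio -0.28, range -0.42 to -0.10, percentile 22.6), with the Polycomb gene SUZ12 1.99-fold (1.88 to 2.12) lower, and higher in 1 and lower in 3 in ldR-H460, where the median of -0.0012 was positive with TMM and DESeq2 factors, with mitochondrially encoded and ribosomal protein UMIs left out of the totals and with G1 cells. Of 27 histone acetylation enzymes 1 was higher and 2 lower in mdR-H460 (median log2 ratio -0.19, range -0.28 to -0.004, percentile 55.5), and 0 higher and 2 lower in ldR-H460 (median log2 ratio 0.05, range -0.07 to 0.18, percentile 93.7), a median that turned negative with cells weighted equally, thinned cells and members at 10 CPM, and the deacetylase gene HDAC9 was 14.8-fold (6.09 to 46.8) lower there.

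To describe the cell cycle, cells at 5000 UMIs were called G1, S or G2M from scores of the S phase and G2/M lists. G2M calls made up 21.8% (20.5% to 23.2%) of H460, 34.3% (32.8% to 35.8%) of mdR-H460 and 40.4% (39.0% to 41.8%) of ldR-H460 cells. G1 calls made up 38.2% (36.7% to 39.8%), 36.4% (34.9% to 37.9%) and 20.9% (19.8% to 22.2%), and S calls 39.9%, 29.4% and 38.7%, in the same order. These calls are ranges of a score rather than cell types, and 602, 579 and 1116 cells (15.6%, 14.9% and 24.7%) lay within 0.05 of the G1 boundary. Cells near the boundary between S and G2M were not counted. With scores centred within each library G2M calls were 29.4%, 37.2% and 38.0%. MKI67 was found in 28.4%, 24.7% and 31.9% of thinned cells, and 41.4%, 38.4% and 53.1% without thinning. In the 3112, 2852 and 3414 cells that could be thinned to 10000 UMIs the shares were 43.3%, 45.4% and 54.0%, with H460 and mdR-H460 in the other order. Cells and depth both differ between these settings, so no order of these libraries is read from them. In CPM the gene had 94.8, 77.7 and 93.4.

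**Figure D3:**
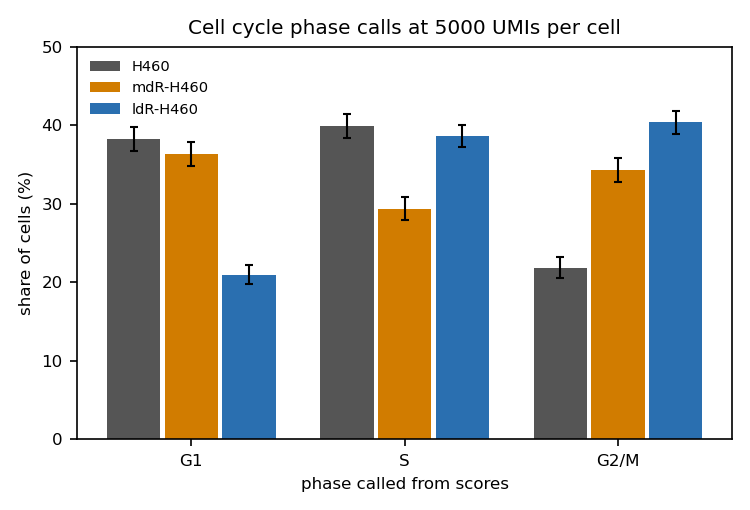
Percent of cells called G1, S or G2M in each library at 5000 UMIs per cell, with exact 95% binomial intervals as bars. G2M calls take 21.8% of H460, 34.3% of mdR-H460 and 40.4% of ldR-H460 cells.

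Because the growth protocol includes irradiated human fibroblasts as feeder cells, the cells were searched for another type. Clustering of all cells gave 8 clusters, of which 6 drew 97.0% to 99.1% of their cells from 1 library and so may stand for that library. The cluster of 222 cells led by HSPA6 and DDIT3 drew 68.5% of its cells from mdR-H460 and none from ldR-H460. Clustering within single libraries also gave a cluster led by HSPA6 in H460 (103 cells, 2.27%) and in mdR-H460 (139 cells, 2.70%). In ldR-H460 no cluster was led by this gene. With 1 library per group these shares describe the libraries only. Another of the 8 clusters, with 1344 cells and a median of 437.5 UMIs, was left unnamed and drew 51.9% from its largest library. No cluster was fibroblast-like by the markers fixed beforehand, and 2 cells, both from H460, carried UMIs of 3 or more fibroblast collagen genes. Of 15 fibroblast markers 6 were measured, and 5 were lower and 0 higher in mdR-H460 than in H460 (median log2 ratio -1.99, range -2.12 to -1.32, percentile 0.08, -1.32 with cells weighted equally), 4 lower and 0 higher in ldR-H460 (median log2 ratio -1.66, range -2.05 to -1.53, percentile 0.12). The proteoglycan gene LUM had 4.65 CPM in H460 and was 34.5-fold (17.9 to 76.0) lower in mdR-H460, and COL3A1 had 2.42, 0.465 and 3.18 CPM. Of 12 immune cell markers 2 were measured, and of 8 endothelial markers 0.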

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

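The alternatives with cells under 4000 detected genes, without cells under 1000 UMIs, without the H460 cluster led by S100A8 and without the cluster led by HSPA6 were chosen after the data had been seen, and the other 13 for counts of genes were chosen beforehand. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. With no replicates, depth limits only the counting error, and low genes carry wide intervals, such as ABCB1 with 2 UMIs in ldR-H460. Removing cells with a mitochondrially encoded share above 10% left out 0 cells and says nothing about stability. Doublets could not be weighed, since the caller marked under 0.5% of cells. No list median at least 1.5-fold from no difference changed sign under any alternative. Among ratios of named genes at least 2-fold apart 4 genes changed sign. FGG in ldR-H460 against H460 had a log2 ratio of 0.028 without the H460 cluster led by S100A8. Without the cluster led by HSPA6 CHAC1 had 0.11 in ldR-H460 against H460 and SESN2 0.12 against mdR-H460. GATA6 in mdR-H460 against H460 had 0.67 with cells weighted equally and 0.27 with thinned cells. Of 1833 alternative values of list medians 1354 stayed within counting error and 479 moved beyond it. For ratios of named genes the numbers were 12387 and 2897 of 15289, and for shares of cells 25 and 113 of 138, where the UMIs per cell and the cells kept differ together. The totals for list medians and named genes include the alternatives on mitochondrially encoded share, marked doublets and fibroblast collagens. These left out 0 or very few cells and could hardly move a value, so the totals do not measure stability. Where no reason is given below, the cause was not tested.

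Expression floors change the number of genes by construction. With floors of 1 CPM, 50 CPM and only above 3 UMIs, genes at least 2-fold higher in mdR-H460 than in H460 numbered 348, 47 and 1028 (117 in the report) and lower 1218, 122 and 2393 (451). In ldR-H460 against H460 they numbered 660, 69 and 1520 higher (218) and 1323, 181 and 2537 lower (523), and in ldR-H460 against mdR-H460 607, 27 and 1477 higher (159) and 522, 75 and 1369 lower (191). With the same 3 floors, transiently higher genes numbered 63, 8 and 299 (22), transiently lower 231, 10 and 467 (64), held higher 243, 26 and 514 (80), held lower 771, 96 and 1473 (299), late higher 258, 26 and 657 (90), late lower 268, 47 and 540 (111) and opposite 46, 4 and 97 (11).

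Leaving mitochondrially encoded and ribosomal protein UMIs out of the totals raises every other CPM and so admits more genes. It gave 345 genes higher in ldR-H460 than in H460 and 273 higher than in mdR-H460, 110 transiently lower and 145 late higher genes. With cells called G1 alone, 263 genes were higher and 348 lower in ldR-H460 than in mdR-H460, and 43 were transiently higher, 151 late higher, 216 late lower and 21 opposite. Transiently higher genes numbered 38 with TMM and 37 with DESeq2 factors, and late lower genes 170 with cells weighted equally. The counts kept of the 568 genes called for mdR-H460 against H460 were 438 with TMM factors, 444 with DESeq2 factors, 411 with G1 cells and 521 with cells under 4000 genes. For ldR-H460 against H460, 643 of 741 were kept with TMM and 652 with DESeq2 factors.

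Few lists had a median at least 1.5-fold away, so small moves changed their number. In mdR-H460 against H460, 1 list was that much higher, but 3 with TMM factors, 2 with DESeq2 factors, 2 with G1 cells, 0 with cells weighted equally and 0 with cells under 4000 genes, and of 6 lists lower, 3 were left with G1 cells. In ldR-H460 against H460, 1 list was higher, 2 with TMM factors, 2 without mitochondrially encoded and ribosomal UMIs and 0 with members at 10 CPM, where 5 lists were lower in place of 8, as without the cluster led by HSPA6. In ldR-H460 against mdR-H460, 1 list was higher, 0 with TMM factors, 0 with DESeq2 factors, 0 with cells trimmed at both ends, 0 with cells under 4000 genes and 2 with G1 cells (the S phase and G2/M lists, which set the G1 call and so say nothing there), and 7 lists were lower with cells weighted equally in place of 4.

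Phase shares moved with the scoring and with the use of all UMIs, which adds the cells under 5000 UMIs and so changes both depth and cells. With scores centred within each library, G1, S and G2M calls were 40.8%, 29.8% and 29.4% in H460 and 27.8%, 34.2% and 38.0% in ldR-H460, and S and G2M calls 25.1% and 37.2% in mdR-H460. With all UMIs of each cell, G1, S and G2M calls were 35.7%, 45.5% and 18.8% in H460, 38.9%, 32.1% and 28.9% in mdR-H460 and 17.2%, 46.3% and 36.5% in ldR-H460. Clustering within single libraries gave 5 clusters in H460, 5 in mdR-H460 and 7 in ldR-H460, against 8 over all cells, which were 10 at resolution 1.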

Other observations

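The tests with cells under 4000 detected genes, without cells under 1000 UMIs and without either cluster were chosen only after the result was seen, while the other scaling factors were planned and only the bounds set for them came after. Further gene groups were compared between the libraries, and several had medians near the middle of those of random lists. Interferon-stimulated genes went both ways in mdR-H460 against H460, 4 higher and 7 lower of 19 (median log2 ratio -0.42, range -0.55 to -0.09, percentile 5.08), with BST2 6.44-fold (4.74 to 8.92) higher and the antiviral synthetase gene OAS1 3.71-fold (3.45 to 3.99) lower. In ldR-H460 6 were higher and 8 lower (median log2 ratio -0.11, range -0.31 to 0.05, percentile 52.8, positive with TMM factors and G1 cells), with the exonuclease gene ISG20 7.43-fold (7.18 to 7.70) lower. DNA repair genes were lower in 10 of 29 and higher in 0 in mdR-H460 (median log2 ratio -0.34, range -0.40 to -0.15, percentile 2.65), among them BRCA1 2.21-fold (2.03 to 2.41) and PALB2 2.57-fold (2.13 to 3.11) lower, and lower in 6 in ldR-H460 (median log2 ratio -0.12, range -0.19 to 0.0022, percentile 50.1, positive with TMM factors). Death members of the apoptosis machinery were higher in 2 and lower in 3 of 15 in mdR-H460 (median log2 ratio -0.15, range -0.26 to 0.17, percentile 43.9, positive with TMM and DESeq2 factors, thinned cells and members at 10 CPM) and lower in 4 in ldR-H460 (median log2 ratio -0.27, range -0.55 to -0.14, percentile 16.6). Survival members were higher in 1 and lower in 2 of 9 in mdR-H460 (median log2 ratio -0.18, range -0.32 to 0.01, percentile 45.4, positive with TMM and DESeq2 factors) and had the same numbers in ldR-H460 (median log2 ratio -0.20, range -0.32 to -0.08, percentile 36.1), with BIRC3 2.76-fold (2.43 to 3.13) lower there. Cholesterol synthesis genes were lower in 5 of 21 in mdR-H460 (median log2 ratio -0.26, range -0.30 to -0.08, percentile 24.5) and in 4 in ldR-H460 (median log2 ratio -0.25, range -0.41 to -0.13, percentile 18.02), with PMVK 1.93-fold (1.86 to 2.01) lower in mdR-H460. WNT pathway genes were lower in 3 of 8 in mdR-H460 (median log2 ratio -0.19, range -0.23 to -0.0048, percentile 57.8) and split in ldR-H460 (median log2 ratio 0.06, range -0.07 to 0.27, percentile 82.6, negative with members at 10 CPM), where the ligand gene WNT5A was 2.61-fold (2.25 to 3.03) higher.

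Of 18 imprinted genes 8 were measured, 5 lower and 1 higher in mdR-H460 (median log2 ratio -0.80, range -0.83 to -0.49, percentile 0.49, -0.49 with members at 10 CPM) and 3 lower and 2 higher in ldR-H460 (median log2 ratio -0.44, range -0.79 to -0.24, percentile 11.1, -0.79 with G1 cells). NDN was 39.9-fold (22.1 to 80.5) lower in mdR-H460 and 12.8-fold (8.92 to 19.1) lower in ldR-H460, and MEST 3.19-fold (3.05 to 3.34) and 3.34-fold (3.19 to 3.50) higher. Lung lineage and neuroendocrine genes were lower in 4 of 8 in mdR-H460 (median log2 ratio -0.54, range -0.58 to -0.05, percentile 5.73, nearest to no difference with cells weighted equally) and in 4 in ldR-H460 (median log2 ratio -0.71, range -0.74 to -0.42, percentile 1.67, -0.42 without mitochondrially encoded and ribosomal protein UMIs and -0.49 without the cluster led by HSPA6), with SOX9 14.6-fold (12.1 to 17.7) lower and the secretoglobin gene SCGB3A2 5.47-fold (4.88 to 6.15) higher in ldR-H460. Of 27 cancer-testis antigens 3 were measured, with 1 lower in ldR-H460 (median log2 ratio -0.58, range -0.63 to -0.46, percentile 7.75) and a median of 0.05 in mdR-H460 that turned negative with cells weighted equally and with thinned cells. Ribosomal protein genes had small medians of 0.05 in mdR-H460 and 0.04 in ldR-H460 over 82 genes (percentiles 3.84 and 77.8). Nuclear oxidative phosphorylation genes had small medians of 0.08 and 0.12 over 84 genes (percentiles 65.0 and 99.7), the latter high among random lists. Histone genes, many of them near-identical copies, had medians of -0.03 and -0.08 over 32 genes, both positive with TMM and DESeq2 factors, the former also without the cluster led by HSPA6 and the latter also without mitochondrially encoded and ribosomal protein UMIs and with G1 cells.

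A first pattern is the set of 80 genes at least 2-fold higher and 299 lower in both derivatives. An upper limit on detected genes per cell that was lower for the ldR-H460 table is inferred only from its maximum. It could not make the mdR-H460 differences, since the H460 and mdR-H460 tables reached 4987 and 4993 genes per cell. It could bear only on the ldR-H460 ratios of these genes. With only cells under 4000 genes, 90.2% of the genes had the same course. Gain or loss of the regions around most of these genes is argued against for mdR-H460 against H460, the only pair compared in this way. Other genes within 1 Mb of the lower genes had a median log2 ratio only -0.0368 (-0.0670 to -0.0167) from that of all genes, over 1568 neighbours of 285 of 299 genes whose own median was -1.61. Around 74 of the 80 higher genes, 492 neighbours differed by 0.0975 (0.0632 to 0.133), while the genes themselves had a median of 1.66. Both small differences lay in the direction of such a gain or loss. Genes of the set were left out of the neighbours, and a median pooled over many regions cannot show a change in a few of them. Gain or loss of a few regions, differences between single cultures, cloning and the shared H460 library stay open as untested, as does the epigenetic change that the series title names.

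A further pattern is that more genes were at least 2-fold lower than higher in mdR-H460 against H460. Scaling to all UMIs may account for a part, since the lower share was 64.5% with TMM factors against 79.4% without, but it stayed above 60%. Leaving out cells under 1000 UMIs gave 79.4% and kept 567 of 568 genes called, which moves too little to decide whether such cells matter. A difference in RNA content per cell and a biological loss of expression stay open as untested.

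Another pattern is a small number of cells that lay, within the 6 clusters drawn almost wholly from 1 library, in a cluster led by another. The clusters of 222 and 1344 cells, which mix libraries, are left aside. Of the 202 cells so placed, 29 of H460 lay in clusters led by mdR-H460, 6 of H460 in those led by ldR-H460, 26 and 61 of mdR-H460 in those led by H460 and ldR-H460, and 10 and 70 of ldR-H460 in those led by H460 and mdR-H460. Barcodes present in both libraries are argued against, since 0% (0% to 1.81%) of these cells shared a barcode with a cell of the leading library, against 0.613% among all other cells. A barcode listed only for the wrong library would not be seen this way, so this comparison cannot decide on such barcodes. Barcodes listed only for the wrong library, cells of intermediate state, and cells placed by chance in the clustering stay open as untested hypotheses.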
